A study of Mus musculus with 8 samples.

How the data were processed

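MicroRNA (miRNA) levels were measured by small RNA sequencing in mouse bone marrow-derived macrophages, which are primary cells grown from bone marrow precursors. Per the labels' protocols, the precursors were differentiated for 6 days with L929 supernatant, a conditioned medium that supplies macrophage colony-stimulating factor. LPS, a bacterial cell wall component sensed by Toll-like receptor 4, was then given at 100 ng/ml. Libraries came from total RNA isolated with Tri Reagent and were made with the TruSeq Small RNA kit, per the labels' protocols. The labels give 3 unstimulated libraries and 3 libraries of cells treated with LPS for 3 h, and these 6 libraries entered every test. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The series also has 2 samples of a chromosome conformation assay (3C-seq) around the miR-155 locus, which were not analysed here.

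The deposited values are counts, 1 whole number per mature miRNA and library, with no normalization by the authors that the values show. The submitters' processing notes name Novoalign, SAMtools 0.1.19 and the assembly GRCm38.p1 (mm10) for these libraries. The counting tool, the miRNA annotation release, the handling of reads that map to several places and the use of strand are not given in the sources used here. Reads that fit several hairpins, or overlapping hairpins on either strand, could therefore have been split, repeated or dropped before the counts were deposited. Each table lists 1907 mature miRNAs, of which 941 had at least 1 count in some library and 966 had 0 counts in all 6. Every entry named a miRNA. Library totals ranged from 3280688 to 4312555 counts. Reads carry no molecular identifiers, so the precision given by depth covers counting error only.

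Hairpin positions were taken from a RefSeq gene table of the assembly GRCm38.p6, a later patch of the assembly named in the processing notes. Of the 1907 mature miRNAs, 1900 matched a hairpin gene by name, and so did all 397 that reached 10 counts in some library. A mature miRNA whose name matched several hairpins (87 of them), or whose hairpin overlapped another annotated hairpin, was treated as uncertain. A gene whose span covers a hairpin is named as such, without saying whether the hairpin lies in an exon or an intron or on which strand, since the table gives spans only.

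Changes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test, TMM scaling factors and the filterByExpr filter with a minimum count of 10. This filter left 357 miRNAs, which held 99.974% of all counts. P-values were adjusted by the Benjamini-Hochberg method over these miRNAs, and an adjusted p below 0.05 was called a change. Levels are CPM, the counts scaled to a common library size with the TMM factors, given as mean ± SD with n = 3 libraries per group. Log2 fold changes are LPS over control with their standard error (SE). TMM factors ranged from 0.96 to 1.053. No pair of libraries within a group agreed within counting noise (chi-square per degree of freedom of 63.0 or more), so none was treated as a repeat deposit of another. Separate preparations of 1 sample would also exceed that noise, so this does not show that the libraries are independent samples.

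Before the data were examined, 19 lists of miRNAs were fixed. They cover miRNAs reported as induced by LPS in macrophages, the miR-99b/let-7e/miR-125a, miR-221/miR-222 and miR-23/27/24 clusters, the let-7, miR-29, miR-17-92, miR-30, miR-181 and miR-15/16 families, miRNAs of alternative activation, of the myeloid lineage and of p53 and hypoxia responses, and markers of erythroid cells, lymphocytes, stromal cells, endothelial and progenitor cells, epithelium and other tissues, and the imprinted cluster on chromosome 12. Each list with at least 3 tested members was compared with all other tested miRNAs by camera (limma 3.58.1) on log-CPM values with a prior count of 2 and a preset correlation of 0.01. An estimated correlation and the fry test were alternatives. For 100 hairpins with both arms past the filter, limma was fitted to the log-CPM of the less abundant arm minus that of the abundant arm within each library, with a variance trend on the level of the less abundant arm. Abundance of arms was ranked by the mean over all 6 libraries. Shares of counts and numbers of detected miRNAs were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

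The miRNAs named in the text were chosen by a rule set before the data were examined. It takes up to 12 miRNAs with the largest rise and up to 12 with the largest fall among those past the threshold with a mean of at least 10 CPM. It adds every tested arm of the LPS-induced and miR-99b cluster lists, the 10 most abundant miRNAs, up to 4 members of each other list with the largest absolute fold change, and up to 6 hairpins with the largest difference between arms past the threshold. Names outside this rule are marked as chosen after their values were seen, except where they are listed only as members of a count.

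The test was tried on simulated data with counts drawn from the means and totals of these libraries. All miRNAs were given 1 common dispersion (0.0229). For the test of recovery, 200 miRNAs above a minimum mean count were changed at once. With 351 simulated miRNAs past the filter, it recovered 76.1% of those changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 5 calls among 151 unchanged miRNAs. With no change simulated it made 0 calls among 353 miRNAs. Changing 200 miRNAs at once eases the adjusted threshold, and real miRNAs differ in their spread. The recovery rates may therefore overstate what the test can find in the real libraries. An uncalled miRNA was not shown to be unchanged. A simulated shift in 1 list ranked that list at place 1 of 17. The simulation set means, totals and a dispersion, but no correlation between members of a list. It therefore cannot tell whether camera's preset correlation of 0.01 suits the real lists. With an estimated correlation all list calls in the real data were lost. Only 1 list was shifted, so recovery of other lists, or of lists with few changed members, is not known. The arm test recovered all 20 of 20 hairpins given a 4-fold difference among 100, with 0 other calls. Smaller differences between arms were not simulated, so recovery at the size of most arm differences reported below is not known.

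Alternatives set before the data were examined were other scalings (DESeq2 1.42.0 size factors, upper-quartile factors, library totals), no filter or a minimum count of 50, a replicate block, leaving out each library, DESeq2's Wald test, limma-voom, a robust fit, leaving out the most abundant miRNA, a minimum fold of 1.2 and an adjusted p below 0.01. Added after seeing the data were a test on single-hairpin miRNAs that overlap no other hairpin, an arm test without the variance trend and an arm test with a prior count of 0.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.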

Results

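Mature miRNA levels were profiled in mouse bone marrow-derived macrophages that were left unstimulated or exposed for 3 h to 100 ng/ml LPS, the bacterial ligand of Toll-like receptor 4. Each condition had 3 libraries. The unstimulated libraries held 4312555, 3912296 and 4010116 miRNA counts and the LPS libraries 3280688, 3992338 and 4105395. Between 684 and 714 miRNAs had at least 1 count in a library, and 335 to 364 had at least 10. Levels are library-scaled counts (CPM), shown as mean ± SD over the 3 libraries of a group. All coordinates are from the GRCm38.p6 assembly.

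The first comparison asked whether LPS altered the overall make-up of the miRNA pool. A few miRNAs dominated the counts in both conditions. Some arms of shared or overlapping hairpins had almost no counts, and how such reads were handled is not known. The ranks and shares below therefore describe the deposited counts and may differ from the levels in the cells. miR-22-3p alone took 23.8% ± 1.97 (SD, n = 3) of control counts and 23.0% ± 1.55 of LPS counts. miR-21a-5p followed with 21.2% ± 3.11 and 22.1% ± 1.84. Next by mean level came miR-27b-3p, miR-191-5p, miR-142a-5p (one arm of a hairpin typical of blood cells), miR-92a-3p, miR-30d-5p, miR-221-3p, miR-10a-5p and miR-222-3p. Of these 10 miRNAs, 1 passed the test for a change, miR-222-3p, whose share was 1.67% ± 0.183 in controls and 2.30% ± 0.309 after LPS. This call was lost in 8 of 19 alternatives, among them the scalings by upper-quartile factors and by library totals.

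Together the 10 most abundant miRNAs held 75.65% ± 0.351 of control counts and 75.41% ± 0.147 of LPS counts, a difference smaller than the control SD (two-sided exact permutation p = 0.4). The number of detected miRNAs was 696.3 ± 9.29 in controls and 699.3 ± 15 after LPS (two-sided exact permutation p = 0.9). With 3 libraries against 3 the smallest p this test can give is 0.1. Log-CPM values of library pairs correlated across miRNAs at 0.991 to 0.993 within a condition and at 0.979 to 0.985 between conditions, and miRNAs are not independent replicates.

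The main comparison asked which miRNAs LPS changed within 3 h. Both arms of miR-155, a miRNA that restrains several inhibitors of inflammatory signalling, rose after LPS. miR-155-5p went from 690.1 ± 411.7 to 4632 ± 497.9 CPM (SD, n = 3 per group), a log2 fold change of 2.75 (SE 0.38). Its partner miR-155-3p went from 4.08 ± 2.24 to 474.3 ± 28.1 CPM, a log2 fold change of 6.85 (SE 0.27) and the largest of all 357 miRNAs tested. Among the miRNAs that fell, miR-27a-5p had the largest fold change, from 96.9 ± 10.2 to 26.0 ± 9.17 CPM (log2 fold change -1.89, SE 0.23). In total 18 miRNAs changed, 13 upward and 5 downward, and 339 did not pass the test.

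The miR-155 hairpin lies on chromosome 16 from 84714140 to 84714204, inside the span of the long noncoding host gene Mir155hg (84713023 to 84715245). Adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000981 for miR-155-5p and 4.11e-08 for miR-155-3p. Control levels of miR-155-5p were uneven, at 1106, 282.5 and 682.0 CPM, and the LPS libraries held 5189, 4230 and 4478 CPM. The counts behind miR-155-3p were 27, 8 and 16 in the control libraries and 1443, 1874 and 1997 in the LPS libraries.

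miR-146a-3p, from the hairpin whose main arm targets the signalling proteins Irak1 and Traf6, rose from 8.94 ± 3.28 to 47.5 ± 5.22 CPM (log2 fold change 2.41, SE 0.26). The main arm miR-146a-5p was already at 17080 ± 1060 CPM in controls and reached 19760 ± 3134 CPM, which did not pass the test (log2 fold change 0.21, edgeR adjusted p = 0.664). The hairpin lies on chromosome 11 from 43374397 to 43374461. miR-455-5p, from a hairpin within the span of the collagen gene Col27a1 on chromosome 4 (63256851 to 63256932), rose from 1.44 ± 0.243 to 7.15 ± 0.889 CPM (log2 fold change 2.28, SE 0.30). Its counts were 5 to 7 in control and 22 to 32 in LPS libraries.

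The minor arms of the miR-99b/let-7e/miR-125a cluster rose as well. This cluster lies within 1 kb on chromosome 17, from 17830188 to 17830879, inside the span of Spaca6. miR-125a-3p went from 24.6 ± 4.96 to 116.7 ± 21.0 CPM (log2 fold change 2.24, SE 0.20), let-7e-3p from 14.8 ± 3.53 to 54.8 ± 9.72 CPM (1.89, SE 0.22) and miR-99b-3p from 106.1 ± 11.01 to 158.8 ± 20.5 CPM (0.58, SE 0.14). The miR-221/miR-222 pair on the X chromosome (19146294 to 19146971), known for restraining the cell cycle inhibitor p27, gave 3 more rises. miR-221-5p went from 2098 ± 125.3 to 3977 ± 268.3 CPM (0.92, SE 0.10), miR-222-5p from 111.2 ± 17.4 to 367.4 ± 116.6 CPM (1.73, SE 0.21) and miR-222-3p from 16350 ± 1180 to 23380 ± 2273 CPM (0.52, SE 0.11). The remaining rises were miR-21a-3p (5690 ± 1228 to 9783 ± 1900 CPM, 0.78, SE 0.18), miR-29b-1-5p (3.04 ± 1.29 to 8.78 ± 2.55 CPM, 1.51, SE 0.36) and miR-210-5p (58.9 ± 3.74 to 86.9 ± 6.13 CPM, 0.56, SE 0.14).

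Besides miR-27a-5p, whose hairpin lies on chromosome 8 from 84208672 to 84208758, 4 miRNAs fell. miR-223-5p, an arm of the myeloid miRNA miR-223 on the X chromosome (96242817 to 96242926), fell from 467.4 ± 97.46 to 257.4 ± 10.3 CPM (log2 fold change -0.86, SE 0.15). miR-3074-1-3p fell from 6.11 ± 1.01 to 1.71 ± 0.383 CPM (-1.82, SE 0.32), and its hairpin on chromosome 13 (63301199 to 63301283) overlaps that of miR-24-1, so its reads could belong to either. miR-26b-3p fell from 66.5 ± 8.65 to 41.2 ± 1.19 CPM (-0.69, SE 0.16). miR-26a-2-3p, which was outside the naming rule and chosen after its values were seen, fell from 10.1 ± 1.32 to 3.05 ± 1.33 CPM (-1.75, SE 0.31).

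**Figure D1:**
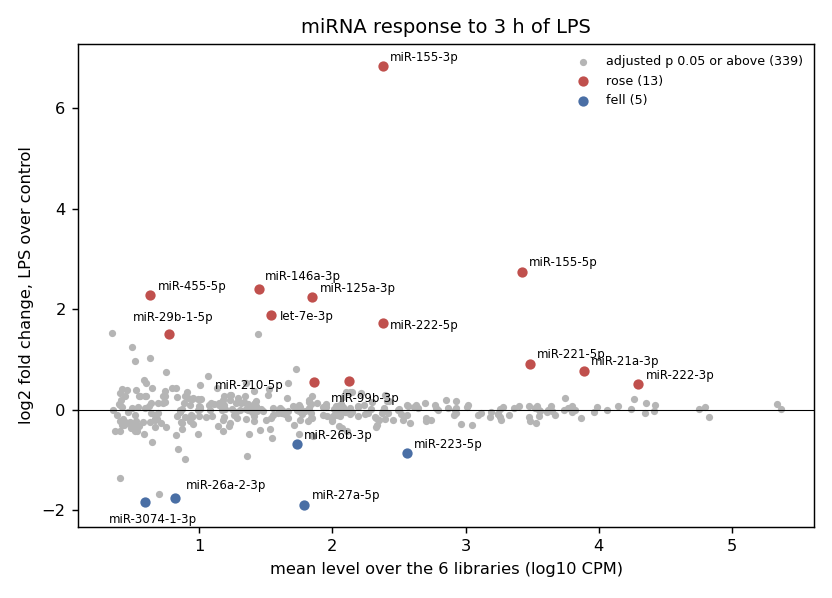
Log2 fold change of LPS over control (vertical axis) against the mean level over the 6 libraries (horizontal axis, log10 CPM) for the 357 tested miRNAs, with 1 point per miRNA. The 13 miRNAs that rose are red, the 5 that fell are blue and the 339 others are grey, and miR-155-3p stands highest at 6.85.

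Adjusted p-values of the 18 calls ranged from 4.11e-08 to 0.0415, and in all 18 the 3 LPS libraries lay beyond the 3 control libraries. Such full separation was seen in 57 of 357 miRNAs (16%), where chance gives 10%. At an unadjusted p below 0.05, 42 miRNAs passed. The count fell from 18 to 11 without LPS replicate 3, where miR-3074-1-3p (edgeR adjusted p = 0.0546) and miR-26a-2-3p (0.0506) were lost. Leaving out any 1 of the 6 libraries ended the calls of miR-99b-3p (adjusted p up to 0.134) and miR-210-5p (up to 0.205), and leaving out any library but control replicate 1 ended that of miR-26b-3p (up to 0.168). Without control replicate 2 or 3 or LPS replicate 1 or 3, the calls of miR-21a-3p (up to 0.0863) and miR-29b-1-5p (up to 0.162) ended, and miR-222-3p was lost without any 1 control library or LPS replicate 2 (up to 0.0995).

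Among groups of miRNAs fixed in advance, camera with its preset correlation called 3 upward relative to the other miRNAs (LPS-induced miRNAs of macrophages, the miR-99b/let-7e/miR-125a cluster and the miR-221/miR-222 pair) and 1 downward (the miR-23/27/24 clusters). With an estimated correlation all 4 calls were lost, with adjusted p = 0.358, 0.194, 0.256 and 0.552 in that order, and 2 lists had an unadjusted p below 0.05. Of 15 tested members of the LPS-induced list, 5 rose (miR-155-5p, miR-155-3p, miR-146a-3p, miR-455-5p and miR-21a-3p), none fell and 10 did not pass. Adjusted over the list alone, 6 rose, miR-147-3p being the other. The 3 rises of 6 tested members in the miR-99b cluster and the 3 rises of 4 in the miR-221/miR-222 pair stayed at 3 and 3 when adjusted over the list alone. In the miR-23/27/24 list 2 of 8 tested members fell (miR-27a-5p and miR-3074-1-3p), and 3 fell when adjusted over the list alone, with miR-23a-5p added. The list has 14 members, and no arm of miR-24 had enough counts to be tested. The fall of miR-3074-1-3p rests on 5 to 8 counts per LPS library.

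Camera's adjusted p-values with the preset correlation were 0.000178 for the LPS-induced list, 0.000175 for the miR-99b cluster, 0.000175 for miR-221/miR-222 and 0.00213 for miR-23/27/24. Fry, which asks whether a list moves one way on balance, called the 3 upward lists (adjusted p = 0.0196, 0.000967 and 0.00737) and not miR-23/27/24 (0.157). The miR-23/27/24 call also ended without control replicate 2 (camera adjusted p = 0.0819), with no filter (0.0701) and with a minimum count of 50 (0.188).

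Several members of the LPS-induced list did not pass the test. miR-147-3p was at 14.3 ± 4.89 CPM in controls and 41.0 ± 21.4 CPM after LPS (log2 fold change 1.51, SE 0.42, edgeR adjusted p = 0.076). It passed without LPS replicate 2 (adjusted p = 0.00124), with a replicate block (0.0112), with DESeq2's Wald test (0.00105) and with no filter (8.52e-10). Its adjusted p reached 0.266 in other alternatives. LPS replicate 2 (16.42 CPM) lay within the control range of 9.22 to 18.99 CPM. The setting with no filter was not tried on simulated data, so its small p-values may not hold. miR-455-3p had a log2 fold change of 1.53 (SE 0.65, adjusted p = 0.351) at 1.11 ± 1.504 and 3.301 ± 0.218 CPM, and passed without control replicate 1 (log2 fold change 3.56, adjusted p = 0.00734) and with no filter (0.0287). miR-21a-5p, the abundant arm within the span of Vmp1 on chromosome 11, had a log2 fold change of 0.12 (SE 0.14), and miR-146b-3p and miR-187-3p of 0.28 (SE 0.38) and -0.27 (SE 0.38). The 4 arms of miR-132 and miR-212, a pair linked to CREB signalling, had log2 fold changes of -0.42 (miR-212-3p), -0.26 (miR-212-5p), -0.12 (miR-132-5p) and -0.07 (miR-132-3p). miR-9-5p and miR-9-3p, outside the naming rule and chosen after their values were seen, had 0 counts in all 6 libraries.

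In the other family lists few members passed. Of 19 tested let-7 arms, let-7e-3p rose, and adjusted over the list alone 2 rose. The second was let-7i-3p, at 38.7 ± 8.40 and 68.1 ± 13.9 CPM (log2 fold change 0.81, adjusted p = 0.0515 over all miRNAs). DESeq2 called it (adjusted p = 0.00517), and it passed without control replicate 2 (0.0213) or LPS replicate 2 (0.016), within a range of 0.000525 to 0.209 over the alternatives for let-7i-3p. Of 7 miR-29 arms, miR-29b-1-5p rose, and adjusted over the list alone 1 rose. None of 18 miR-17-92 arms, 8 miR-30 arms, 8 miR-181 arms or 11 miR-15/16 arms passed by edgeR, over all miRNAs or adjusted over the list alone. At an unadjusted p below 0.05 these were miR-25-5p (log2 fold change -0.98, SE 0.31) and miR-30c-1-3p (-0.92, SE 0.29), and DESeq2 called miR-30c-1-3p (adjusted p = 0.047). miR-25-5p passed without LPS replicate 1 (0.0303). miR-30c-1-3p passed without LPS replicate 2 (0.0156) and with a replicate block (0.0347). With no filter, a setting not tried on simulated data, miR-25-5p and miR-30c-1-3p passed (0.0473 and 0.00459). Camera's adjusted p-values for these 6 lists ranged from 0.61 to 0.984. Median and mean log2 fold changes differed in sign for let-7 (-0.03 and 0.12), miR-17-92 (0.05 and -0.01) and miR-30 (0.01 and -0.10). Arms shared by several hairpins may be undercounted in these lists, so a change of such arms could have been missed. miR-181a-5p had 10 to 17 counts per library. miR-30c-5p, chosen after its values were seen, had 4 to 9 and was not tested.

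Lists of macrophage state held 2 of the changed miRNAs. Of 5 tested myeloid arms miR-223-5p fell, and miR-22-3p, miR-22-5p, miR-142a-5p and miR-223-3p had log2 fold changes from 0.01 to 0.11. Of 5 p53 and hypoxia arms miR-210-5p rose, with miR-34a-5p at 0.18 (SE 0.12) and miR-34c-5p at -0.10 (SE 0.16). Counts adjusted over the list alone were again 1 and 1. None of the 9 tested arms reported in alternative activation passed by edgeR (also adjusted over the list alone), DESeq2 or limma-voom, and 1 (miR-342-5p, -0.34, SE 0.13) had an unadjusted p below 0.05, with miR-511-5p, from a hairpin in the span of the mannose receptor gene Mrc1, at -0.39 (SE 0.18) and miR-378c at 0.19 (SE 0.20). Camera's adjusted p-values were 0.778 for the myeloid list, 0.61 for p53 and hypoxia and 0.778 for alternative activation. The myeloid median was 0.02 with a mean of -0.14, and those of alternative activation were 0.05 and -0.03.

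Markers of other cell types had too few counts to test or did not pass. Erythroid miRNAs summed to 0 to 5 counts per library and the 82 arms of the imprinted chromosome 12 cluster also to 0 to 5, so neither list was tested. None of 3 lymphocyte, 5 stromal, 6 endothelial and progenitor and 6 epithelial and other arms passed by edgeR, over all miRNAs or adjusted over the list alone (camera adjusted p = 0.778 for each list). DESeq2 and limma-voom called none of them either, and 1, miR-125b-1-3p, had an unadjusted p below 0.05 (log2 fold change 0.97, SE 0.35). The lymphocyte miRNA miR-150-5p was at 62.3 ± 7.89 and 71.8 ± 7.12 CPM. The stromal list was made up almost wholly of miR-10a-5p, at 22880 ± 4262 and 22010 ± 1023 CPM. Only 5 of the 16 stromal arms and 6 of the 11 endothelial and progenitor arms passed the filter. A high level of a single member therefore does not show that such cells were present. The progenitor miRNA miR-99a-5p was at 3138 ± 287.5 and 2847 ± 198.1 CPM, and the epithelial miR-141-3p was at 126.1 ± 15.7 and 122.9 ± 17.7 CPM.

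**Figure D2:**
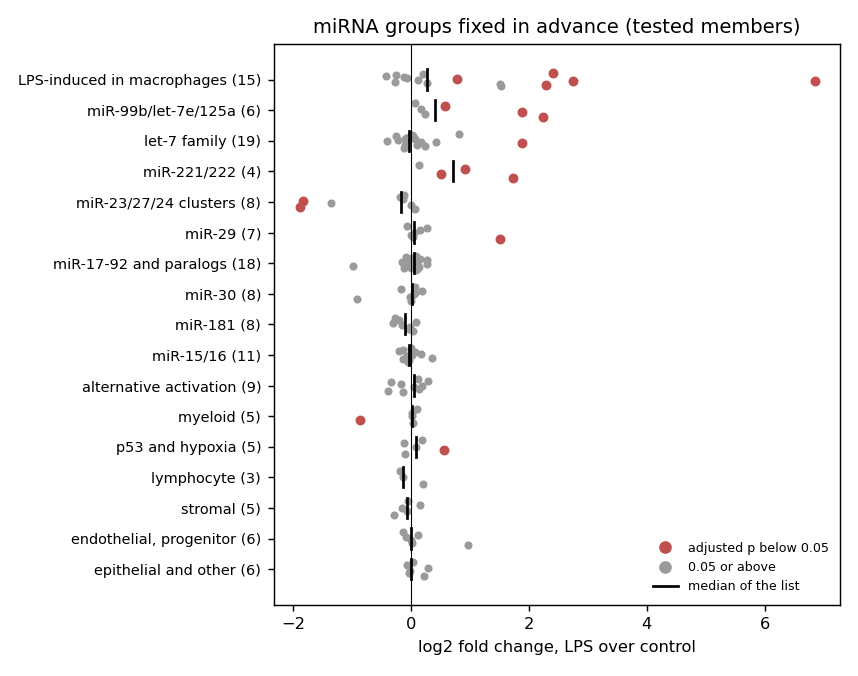
Log2 fold change of LPS over control (horizontal axis) for the tested members of 17 miRNA groups (1 line each, with the number of tested members), where red points passed the test, grey points did not and black bars mark group medians. The miR-221/miR-222 median lies at 0.72 and the miR-99b cluster median at 0.41.

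The last comparison asked whether the 5p and 3p arms of a hairpin changed equally. In 12 of 100 hairpins they did not, and in 9 of these the less abundant arm gained on the abundant one. miR-155-3p made up 0.608% ± 0.065 of the miR-155 counts in controls and 9.35% ± 1.10 after LPS (SD, n = 3), a difference between arms of 3.87 on the log2 scale (SE 0.20). miR-146a differed by 2.21 (SE 0.27), miR-125a by 1.97 (SE 0.22), let-7e by 1.70 (SE 0.25) and miR-222 by 1.17 (SE 0.19). In miR-27a the less abundant arm lost ground, from 2.84% ± 0.29 to 0.737% ± 0.25 of the hairpin's counts, a difference of -2.01 (SE 0.23).

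The other 6 hairpins past the threshold were miR-221 (0.79), let-7i (0.79), miR-21a (0.66), miR-674 (0.65), miR-26b (-0.70) and miR-223 (-0.95), with values as differences between arms on the log2 scale. In miR-674, outside the naming rule, neither arm passed the test by itself. For miR-221 the less abundant 5p arm went from 8.90% ± 1.00 to 14.4% ± 0.57 of the counts of the hairpin, and for miR-21a the 3p arm went from 2.64% ± 0.16 to 4.13% ± 0.47. The abundant arms of miR-125a, let-7e and miR-99b had log2 fold changes of 0.24 (SE 0.16), 0.17 (SE 0.12) and 0.07 (SE 0.10), those of miR-27a and miR-223 0.07 (SE 0.12) and 0.04 (SE 0.25), and none of the 5 passed. Over all 100 hairpins the median difference between arms was 0.03, with 53 above 0.

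**Figure D3:**
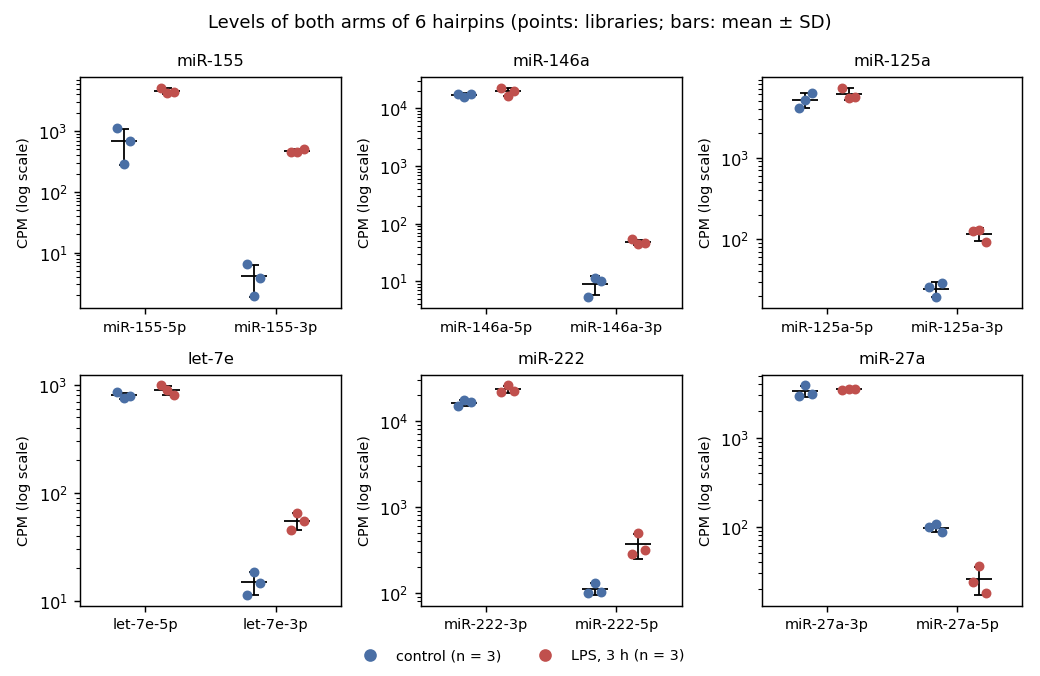
CPM on a log axis for the abundant arm (left) and less abundant arm (right) of 6 hairpins, with 1 point per library (blue control, red LPS, n = 3 each) and bars for mean ± SD. In miR-146a the abundant arm lies at 17080 and 19760 CPM while the less abundant arm lies at 8.94 and 47.5 CPM.

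Limma's adjusted p-values for the 12 hairpins were all below 0.05 and reached 0.0315, for miR-674 and let-7i, and 17 hairpins passed at an unadjusted p below 0.05. A fit without the variance trend, added after seeing the data, called 7 hairpins. Leaving out 1 library ended 5 of the arm calls, with limma adjusted p-values up to 0.287 for let-7i (any library but control replicate 2) and 0.287 for miR-223 (control replicate 1 or LPS replicate 2). They reached 0.0964 for miR-26b (control replicate 2 or 3 or LPS replicate 1 or 2), 0.198 for miR-674 (control replicate 3 or LPS replicate 2 or 3) and 0.0747 for miR-21a (LPS replicate 3).

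**Figure D4:**
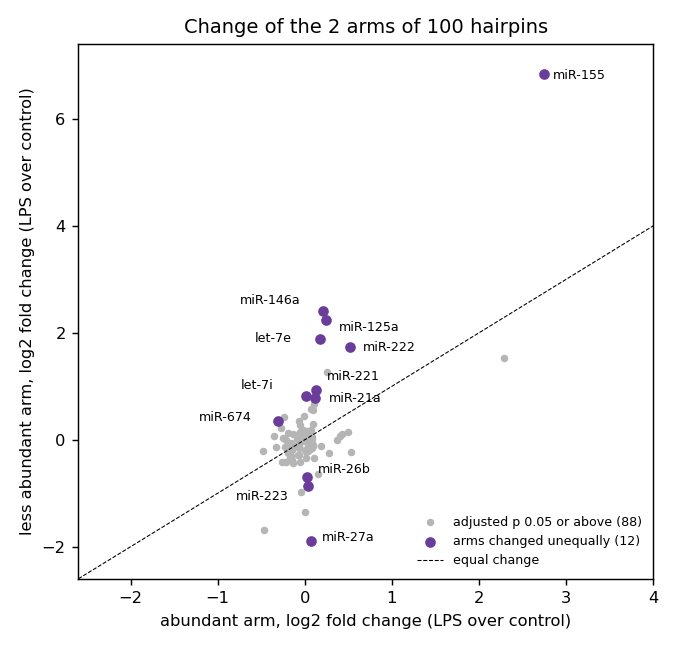
Log2 fold change of LPS over control of the less abundant arm (vertical axis) against that of the abundant arm (horizontal axis), with 1 point per hairpin for 100 hairpins. The 12 purple hairpins changed unequally and lie off the dashed line of equal change, with miR-155 at 6.85 against 2.75.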

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

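The arm fits without the variance trend or with a prior count of 0.5 and the test of single-hairpin miRNAs were chosen after the data had been seen. Across the alternatives the count of 18 changed miRNAs ranged from 11 to 26. It was 19 with DESeq2 size factors, 13 with upper-quartile factors, 15 with library totals, 26 with no filter, 21 with DESeq2's Wald test and 18 with limma-voom. Leaving out 1 library gave 11 to 18, with 11 without LPS replicate 3, and fewer samples were then tested. Of the 18 calls, 10 were kept in every alternative that tested them and 8 were lost in at least 1, and no call changed sign. Changed lists numbered 3 or 4, except 0 with an estimated correlation. Hairpins with unequal arms ranged from 8 to 14 when 1 library was left out, and were 7 without the variance trend. The cause of these last shifts was not tested. The labels do not say whether equal replicate numbers pair the samples, and the counts showed no clear pairing. Correlations of same-numbered deviations were 0.025, 0.144 and -0.04, and not every sample correlated best with its own number. With so few libraries a pairing cannot be excluded. With a replicate block 17 miRNAs were called, 15 of them shared with the 18, along with 4 lists and 11 hairpins. The block added miR-147-3p (edgeR adjusted p = 0.0112) and miR-30c-1-3p (0.0347). It ended the calls of miR-99b-3p (0.0723), miR-210-5p (0.0723) and miR-29b-1-5p (0.0808). The median log2 fold change of all miRNAs was 0.009, and -0.049, -0.045 and 0.004 with upper-quartile factors, library totals and DESeq2 size factors. Low miRNAs rest on few counts, such as 5 to 7 per control library for miR-455-5p.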

Other observations

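The tests of noise between libraries, of equal arm gains and of reads left out of shared arms were chosen after their values were seen. So were all miRNAs named here that the naming rule does not cover. The miR-147 hairpin lies in the span of AA467197 on chromosome 2 (122640803 to 122640881). Its arm miR-147-5p, which was below the filter and so was not tested, had 1, 2 and 0 counts in control libraries and 15, 8 and 22 in LPS libraries. The other arm, miR-147-3p, had 80, 38 and 60 against 176, 67 and 200 counts. The falling miR-26b-3p and miR-26a-2-3p come from hairpins in the spans of the related phosphatase genes Ctdsp1 on chromosome 1 (74394310 to 74394394) and Ctdsp2 on chromosome 10 (126995530 to 126995613). The abundant arm miR-26b-5p had 19547 to 25021 counts per library and did not pass the test (log2 fold change 0.03, edgeR adjusted p = 0.972).

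In the miR-23/27/24 list, 1 member on chromosome 8 and 1 on chromosome 13 fell. On chromosome 8 the less abundant arms miR-27a-5p and miR-23a-5p had log2 fold changes of -1.89 (SE 0.23) and -1.36 (SE 0.45, edgeR adjusted p = 0.178). Their abundant partners miR-27a-3p and miR-23a-3p were at 0.07 (SE 0.12) and 0.00 (SE 0.18). On chromosome 13, miR-3074-1-3p fell (-1.82, SE 0.32, edgeR adjusted p = 0.00599), with reads that could belong to the overlapping miR-24-1 hairpin, and miR-27b-5p, miR-27b-3p and miR-23b-3p were at -0.19 (SE 0.12), -0.14 (SE 0.12) and -0.12 (SE 0.16). The difference between the clusters was not tested.

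After LPS the less abundant arm had the larger absolute log2 fold change in 68 of 100 hairpins. This number lay within the 95% range of 51 to 70 that the standard errors of the arms give with no change at all. These errors hold the whole spread between libraries, so that spread may account for the number. Counting noise alone was not tested. That range covers the count over all 100 hairpins and not the 12 whose arms differed by limma's test. Another candidate explanation is that new hairpins added about as many counts of both arms to a large standing pool of the abundant arm. For the 9 hairpins with a called rising minor arm, the gain of the less abundant arm was subtracted from that of the abundant arm. The 95% interval of this difference excluded 0 in 2. Gains were 3940 and 470 CPM in miR-155 and 7040 and 256 CPM in miR-222, so equal gains in counts were not seen there. Whether both arms of a hairpin are captured equally well in the libraries was not tested. The interval included 0 in 7, but it could be wide. In miR-146a it ran from -2660 to 7930 CPM, where the less abundant arm gained 38.6 CPM. In miR-221 it ran from -2330 to 2590 CPM, against a gain of 1880 CPM. Inclusion of 0 therefore cannot show equal gains in the 7. Neither synthesis nor decay of RNA was measured.

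The falls of 5 miRNAs, 3 of them less abundant arms of hairpins with both arms tested, were set against a general loss of such arms and against the shallowest library. The median log2 fold change of all 100 tested less abundant arms was 0.009 (95% bootstrap interval -0.059 to 0.071), far from the size of the falls. Without LPS replicate 1, the shallowest library, the median log2 fold change of the 5 was -1.867, against -1.754 with it. Leaving out LPS replicate 1 ended the call of miR-26b-3p. Leaving out LPS replicate 3 ended the calls of miR-3074-1-3p, miR-26a-2-3p and miR-26b-3p. The median over the 100 arms argues against a general loss as the cause of the 3 falls among them. The median without LPS replicate 1 cannot decide about the shallowest library. In all 5 falls every LPS library lay below every control library, so leaving 1 out could hardly shrink it. A biological response to LPS remains a hypothesis.

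Several arms shared by more than 1 hairpin had low counts. miR-24-3p had 0 or 1 count per library, miR-181a-5p 10 to 17 and miR-30c-5p 4 to 9, while miR-92a-3p, also shared, had 81732 to 113719. Reads that map to several loci may have been left out of the counts. The shared arm lay below its locus-specific partner arms in 6 of 13 cases. The share to be expected without such a loss is not known, so this count cannot decide it. The level of miR-92a-3p goes against a full loss of such reads. miR-142a-3p had 0 counts in all 6 libraries beside 196331 to 238828 for miR-142a-5p, and its hairpin lies inside the annotated span of Mir142b, so levels of shared or overlapping arms may be understated, and no biological explanation was tested.

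The 6 libraries can be split 3 against 3 in 10 ways, too few for a share below 0.05. The real split gave 18 changed miRNAs and the highest other split 1, so that 1 split, the real one, gave as many. For lists the real split gave 4 and the highest other also 4, so 2 splits gave as many. For hairpins with unequal arms the real split gave 12 and the highest other 0, so 1 split gave as many.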
